A study of Danio rerio with 19 samples.

How the data were processed

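RNA sequencing was done on whole zebrafish larvae kept in a control medium, named ERM in the labels, or exposed to atorvastatin (AVS) or to afidopyropen (Afid), each at 100 ng/L (low) or 1 µg/L (high). The 19 samples comprise 4 control, 4 AVS high, 4 AVS low, 4 Afid high and 3 Afid low libraries. Per the labels' protocols, total RNA was isolated with TRIzol, messenger RNA was selected on its poly(A) tail, and directional libraries were sequenced on a NovaSeq instrument. The labels do not say whether replicates are separate tanks, clutches or pools of larvae, so p-values measure the spread between these libraries, which may be partly technical.

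Per the submitters' processing notes, fastp, HISAT2, featureCounts and DESeq2 were used by the authors. Their versions, settings and strand option, and the genome build of the coordinates, are not given in the sources used here. Per the file headers, 3 tables deposited by the authors hold raw read counts per gene for AVS high, AVS low and Afid low, each beside the same 4 control libraries, and they list genes with at least 2 reads over the libraries of the table. The control counts were identical in the 3 tables (0 genes differed). Per the file headers, all 4 deposited tables also hold the authors' log2 fold change, p-value and adjusted p-value per gene. Of the Afid high comparison only these values of the authors were used, with no values per library. The authors' tables write an adjusted p of 1 for 89.2% of the 25853 genes of the Afid high table, including genes with p-values down to 1.69e-06, so an adjusted p of 1 there was read as not given. The 46 further columns of normalized values per sample were not used.

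The 15 libraries with counts held 8.63 to 18.6 M reads in genes, with a mean of 13.1 M ± 2.90 (SD, n = 15). Means were 15.5 M ± 2.28 (SD, n = 4) in the control, 11.6 M ± 2.87 (SD, n = 4) in AVS high, 13.5 M ± 3.37 (SD, n = 4) in AVS low and 11.5 M ± 1.11 (SD, n = 3) in Afid low. The mitochondrial genome took 4.19% ± 0.456 of reads (SD, n = 15), and ribosomal protein genes took 8.06% ± 1.61 (SD, n = 15). No pair of libraries of a group was a duplicate: over 21 pairs the chi-square per degree of freedom of their counts was at least 7.76.

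The groups, the tests, the gene lists, the rule for named genes and the alternatives to these steps were fixed before the data were examined. Each exposed group was compared with the control by edgeR 4.0.16 (quasi-likelihood test, TMM scaling, low counts removed by filterByExpr) in R 4.3.3, on the libraries of its own table, with Benjamini-Hochberg adjustment and a threshold of 0.05. AVS high was compared with AVS low in 1 fit of the 15 libraries with counts over the genes listed in all 3 count tables. That fit was planned with 19 libraries, and Afid high against Afid low, planned in the same fit, was not run, since no counts per library were used for Afid high. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives, and DESeq2 run here called the same 61, 43 and 15 genes as the authors' deposited tables. Values per library are counts per M (CPM) after TMM scaling, and fold changes are given as log2 with a standard error (SE). The SE was derived here as the size of the log2 fold change divided by the square root of edgeR's F statistic.

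Gene lists numbered 37, of pathways, organelles and cell types. Apart from the ribosomal proteins, which were taken by symbol, 1117 members were fixed, of which 983 are listed in a table. Symbols were matched with their case. The respiratory chain genes NDUFA13 and NDUFB1, written in capitals in the deposited tables, are therefore missing from their list. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over 148 tests against the control and over 37 tests between the AVS doses, with camera at an estimated correlation and fry beside it. In the comparisons with counts, the estimated correlation of called lists ran from 0.092 (sterol sensing and uptake, AVS low) to 0.82 (ribosomal proteins, Afid low). The preset thus treats members that vary together as nearly independent, and its p-values are too small for such lists. For Afid high, camera was run on a signed normal score made from the authors' deposited p-values and fold changes, over symbols that were tested in another table, and no estimated correlation could be had without values per library. Members of each list were also adjusted over the list alone. The score of a list in a library is the median over its members of log2 CPM (prior count of 2) centred on the mean over libraries.

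Genes named were, by the fixed rule, the 10 of smallest p in each direction among genes past the threshold, or, where fewer than 5 genes pass, the 5 of smallest p in each direction with a gene symbol, a mean of at least 20 reads in 1 group and no overlap between groups. The rule adds up to 4 passing members of each list, or the 2 members of smallest p of a called list, and 8 sterol genes and 3 TRP channel genes in every comparison. Up to 10 genes per direction past the threshold of the authors' deposited tables were added after their values were seen, as were genes shared between tables and genes that a count of 5 or fewer refers to. Near-identical neighbours such as prss60.2 and prss60.3, the crystallins and the keratins can share reads, and without the strand option reads of overlapping genes cannot be assigned with certainty, so their values are uncertain.

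Alternatives were DESeq2 size factors, no low-count filter, DESeq2, limma-voom, the replicate number as a block, all libraries with counts in 1 fit, and each library left out in turn. A fit corrected for the trend of fold change with gene length, DESeq2 with each library left out, a Benjamini-Hochberg adjustment over all listed genes, preset correlations of 0.1 and 0.3 for Afid high, and a fit of the block's libraries without the block were added after seeing the data. A library of a group of 4 was said to stand apart where its gap to the nearest other, divided by the range, was above Dixon's 95% value of 0.829. Group labels were also reassigned over the libraries in 35 splits per comparison. Comparisons share their control libraries, so correlations between them were set against 20 simulations of unchanged groups and against comparisons that share no control library. In these simulations all libraries, controls included, were drawn from a common mean per gene, each gene independently. For pairs with Afid high the simulated libraries had equal depth. The edgeR step was tested on simulated data with 200 changed genes. In the simulation of AVS high, with 18563 genes, it recovered 44% of 2-fold and 94% of 4-fold changes with 12 false calls, and DESeq2 recovered 54% and 96% with 32. In that of AVS low, with 18949 genes, edgeR recovered 44% and 96% with 11 false calls and DESeq2 60% and 97% with 31. In that of Afid low, with 19102 genes, edgeR recovered 34% and 92% with 11 and DESeq2 53% and 95% with 35. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.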

Results

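Messenger RNA of whole zebrafish larvae was measured in 19 libraries: 4 of a control medium, 4 of atorvastatin at 1 µg/L (AVS high), 4 of atorvastatin at 100 ng/L (AVS low), 4 of afidopyropen at 1 µg/L (Afid high) and 3 of afidopyropen at 100 ng/L (Afid low). Atorvastatin is a cholesterol-lowering drug that inhibits HMG-CoA reductase, and afidopyropen is an insecticide that acts on TRPV channels of insects. Read counts of 15 libraries were used, with 8.63 to 18.6 M reads in genes each. For Afid high, the authors' fold changes and p-values were used. The tables address which transcripts differ between each exposure and the control medium.

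Among the control libraries, digestive genes were lowest in replicate 2. In control replicate 2 the score of the exocrine pancreas list was −1.82 against −0.23 to 0.61 in the other 3 control libraries, and that of the intestine list was −1.73 against −0.20 to 0.41. Its liver score was −0.90 and its neuron score 0.47, the highest neuron score of the 15 libraries. Ribosomal protein genes took 11.7% of reads in control replicate 4 and 7.24% to 9.66% in the other control libraries, and 5.40% in AVS low replicate 5. The first 2 principal components held 21.6% and 18.0% of the variance, and on the second control replicate 2 lay at 58.7 while the other 14 libraries lay between −23.4 and 17.6.

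**Figure D1:**
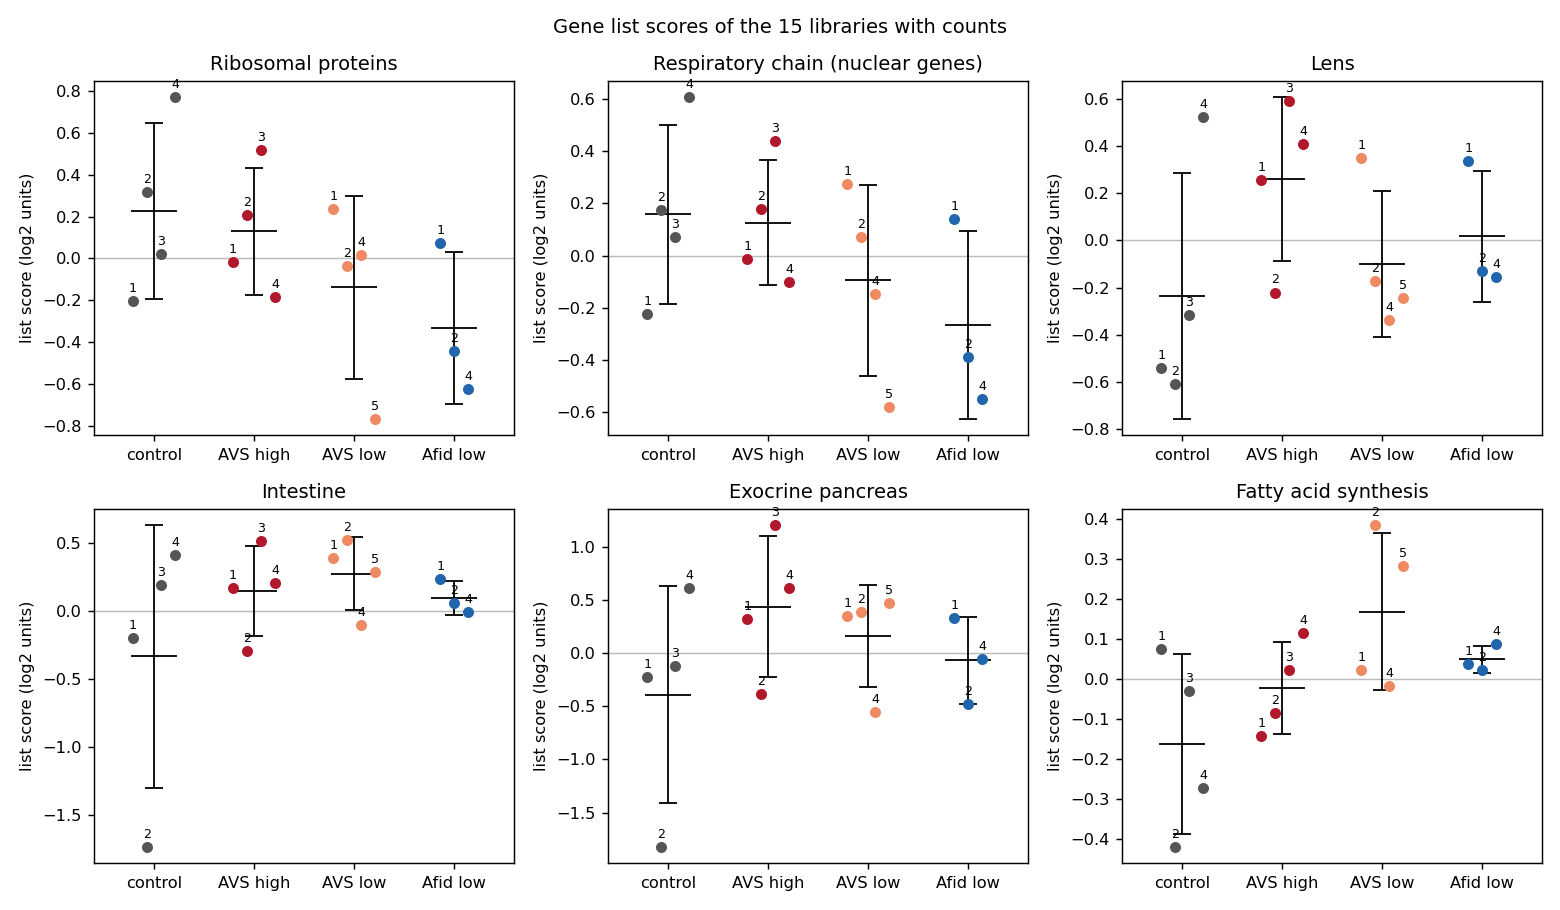
Scores of 6 gene lists (median over members of log2 CPM, centred on the mean of the 15 libraries; y axis in log2 units) by group, 1 numbered point per library, with the group mean and SD as bars. Control replicate 2 lies lowest for intestine (−1.73) and exocrine pancreas (−1.82), and control replicate 4 lies highest for ribosomal proteins (0.77).

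By DESeq2, 53 genes fell and 8 rose in AVS high in the authors' deposited table, while edgeR called 0 genes. Of the 53 lower genes in the authors' deposited table, 1 is in the neuron list, the glutamate transporter slc17a6a (log2 fold change −0.97). Others among the lower ones in the authors' deposited table were slc12a5b, a potassium-chloride cotransporter of neurons (log2 fold change −1.44, adjusted p = 5.84e-06), the G protein subunit GNAZ (−1.06), the histone demethylase kdm6bb (−0.999), the sorting receptor SORCS3 (−1.63) and the guidance receptor epha4b (−1.21). The 8 higher ones in the authors' deposited table included the pancreatic carboxypeptidase cpb1 (1.03), the heat shock protein hspa4b (2.11), the desaturase fads2 (1.22) and growth hormone, gh1 (2.07).

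In the edgeR fit of AVS high, slc12a5b (ENSDARG00000078187; chromosome 8, 37280532 to 37391372, build not given in the sources used here) stood at 20.9 ± 5.76 CPM (SD, n = 4) against 57.0 ± 9.18 CPM in the control (SD, n = 4), a log2 fold change of −1.45 (SE 0.22). GNAZ stood at 9.56 ± 0.900 against 20.1 ± 2.88 CPM (−1.07, SE 0.18), kdm6bb at 24.7 ± 3.65 against 49.7 ± 10.3 CPM (−1.01, SE 0.18), and prkar1ab, a regulatory subunit of protein kinase A, at 7.39 ± 1.06 against 16.3 ± 3.24 CPM (−1.14, SE 0.22), each SD with n = 4. SORCS3 was at a log2 fold change of −1.63 (SE 0.32), hivep3a at −1.12, srgap3 at −1.13, prdm2a at −1.09 and mpp2a at −0.91. Of genes with higher values, lrig3 was at 1.03 (SE 0.24), cpb1 at 1.02 (SE 0.25), hspa4b at 2.096 (SE 0.53), ldlrb, a receptor for low-density lipoprotein, at 0.88 (SE 0.22) and the lens gene crygm2d12 at 1.196 (SE 0.32). None of these passed: edgeR called 0 of 18929 genes, with a smallest adjusted p of 0.139, 1657 genes at unadjusted p under 0.05 where chance gives 946.5, 0 genes by limma-voom and 61 by DESeq2. Of the 1657 genes, 637 were higher and 1020 lower. The groups did not overlap in 983 genes, 5.19% where chance gives 2.86%. The DESeq2 count was 2 without AVS high replicate 4, 3 without control replicate 1, 24 without control replicate 3, 97 without AVS high replicate 2 and 290 without AVS high replicate 1. Without a low-count filter edgeR called 2 genes, slc12a5b and zgc:158463.

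**Figure D2:**
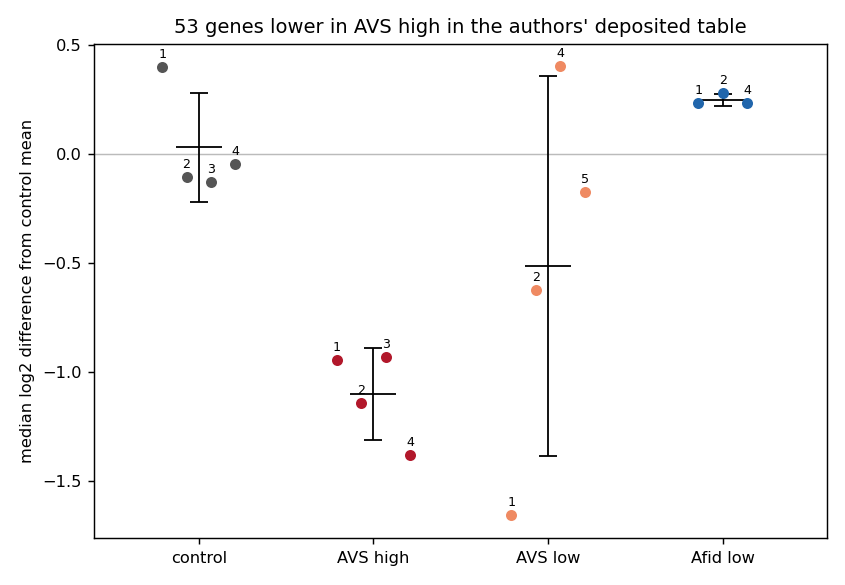
Median over the 53 genes that fell in AVS high in the authors' deposited table of the log2 difference from the control mean (y axis), 1 numbered point per library, with the group mean and SD as bars. The AVS high libraries lie between −1.38 and −0.93, the AVS low libraries between −1.66 and 0.40, and the Afid low libraries between 0.23 and 0.28.

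Lens genes rose in AVS high, with 35 of 39 members higher and a median log2 fold change of 0.45 (camera, adjusted p = 3.06e-11 at the preset correlation, adjusted p = 0.958 with an estimated correlation of 0.65). Among them crybb1l1, a beta crystallin, stood at 1772 ± 778 CPM (SD, n = 4) against 793 ± 260 (SD, n = 4). Exocrine pancreas genes rose, with 19 of 20 higher and a median of 0.74 (adjusted p = 3.42e-07, and adjusted p = 0.958 with an estimated correlation of 0.82), and a median of 0.32 without control replicate 2, in which this list was lowest. Bone and cartilage matrix genes rose, with 27 of 29 higher and a median of 0.31 (adjusted p = 1.51e-06, and adjusted p = 0.958 with an estimated correlation), led by col10a1a, a collagen of hypertrophic cartilage (1.77, SE 0.57), and matn1 (0.76, SE 0.25).

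A further 7 lists passed in AVS high at the preset correlation, each with adjusted p = 0.958 with an estimated correlation, and all 7 calls ended without control replicate 2. Higher were xenobiotic metabolism (30 of 38 members, median 0.26, 0.03 without that library), intestine (20 of 24, 0.38, then 0.05), skin keratins (20 of 23, 0.26, then 0.25), sterol sensing and uptake (10 of 13, 0.16, then 0.20) and liver (19 of 27, 0.11, then −0.06). Lower were neurons (31 of 45, −0.14, then −0.07) and photoreceptors (35 of 47, −0.13, then −0.04). Named members were abcb5 (0.58) and cyp1c1 (0.70) for xenobiotic metabolism, cubn (0.53) and cdx1a (0.63) for intestine, krt8 (0.36) and krt1-19d (0.51) for skin, srebf2, the transcription factor of the sterol response (0.50), ahsg2 (0.75) and serpina1 (0.38) for liver, the glutamate transporter slc17a6a (−0.98) and elavl3 (−0.72) for neurons, and cnga3a (−0.89) and pde6ha (−0.68) for photoreceptors. Without AVS high replicate 3 the calls for intestine (0.15), liver (0.10), skin (0.04), neurons (−0.10) and photoreceptors (−0.03) ended. Without AVS high replicate 1 those for sterol sensing (0.16), liver (0.21) and neurons (−0.16) ended. Sterol sensing also lost its call without AVS high replicate 4 (0.11), skin without control replicate 1 (0.21), and photoreceptors without control replicate 3 (−0.12) or 4 (−0.09). The number of lists called was 10, and 3 without control replicate 2. Over the 37 lists, 6 members passed adjusted over the list alone and 0 over all genes. With fry 0 lists passed, with a smallest adjusted p of 0.778.

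By DESeq2, 37 genes rose and 6 fell in AVS low in the authors' deposited table, while edgeR called 0 genes. The higher ones in the authors' deposited table included fads2, a desaturase of fatty acid synthesis (log2 fold change 1.301, adjusted p = 0.00784), the elongase elovl6l (0.81), the collagen gene col1a1a (1.33), growth hormone, gh1 (1.97), and the trypsin-like genes prss60.3 (2.73) and prss60.2 (1.90). The lower ones in the authors' deposited table included grk1b, a kinase of photoreceptors (−0.98), txndc9 (−0.95), gtf2f2a (−1.10) and sybl1 (−1.83).

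In the edgeR fit of AVS low, fads2 (ENSDARG00000019532; chromosome 25, 4133488 to 4148719) stood at 47.4 ± 6.77 CPM (SD, n = 4) against 19.3 ± 7.85 CPM in the control (SD, n = 4), a log2 fold change of 1.29 (SE 0.26). The gene col1a1a stood at 263 ± 84.7 against 105 ± 30.3 CPM (1.32, SE 0.27), elovl6l at 30.3 ± 5.03 against 17.4 ± 0.720 CPM (0.80, SE 0.17), and prss60.3 at 2.81 ± 1.12 against 0.425 ± 0.208 CPM (2.70, SE 0.52), each SD with n = 4. Further higher values were 1.88 for prss60.2, 3.36 for itgam, 0.88 for rgl3a, 1.09 for klf2b, 1.29 for rhov and 1.05 for oclnb. On the lower side txndc9 was at −0.95 (SE 0.19), grk1b at −0.98 (SE 0.22), gtf2f2a at −1.11 (SE 0.26), nucb2a at −0.83 (SE 0.20), sybl1 at −1.83 (SE 0.44), and guca1c, a calcium sensor of photoreceptors, at −0.79 (SE 0.18). None passed: edgeR called 0 of 19267 genes, with a smallest adjusted p of 0.351, 1949 genes at unadjusted p under 0.05 where chance gives 963.4, 0 genes by limma-voom and 43 by DESeq2. Of the 1949 genes, 991 were higher and 958 lower, so the excess of higher genes among the DESeq2 calls is not seen there. The groups did not overlap in 845 genes, 4.39% where chance gives 2.86%. The DESeq2 count was 3 without AVS low replicate 2, 9 without control replicate 2, 11 without AVS low replicate 5, 14 without control replicate 3 and 796 without AVS low replicate 4.

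Ribosomal protein genes fell in AVS low, with 71 of 74 members lower and a median of −0.42 (camera, adjusted p = 6.89e-12 at the preset correlation, adjusted p = 0.958 with an estimated correlation of 0.80), and −0.16 without control replicate 4, which had the highest ribosomal share. With the trend of fold change with gene length removed the median was −0.30. Among these, rpl35 was at −0.75 and rpl29 at −0.92. Bone and cartilage matrix genes rose, with 26 of 29 higher and a median of 0.39 (adjusted p = 3.47e-08, and adjusted p = 0.958 with an estimated correlation), col10a1a being at 2.13 (SE 0.60). Photoreceptor genes fell, with 39 of 47 lower and a median of −0.26 (adjusted p = 4.95e-06, and adjusted p = 0.958 with an estimated correlation), and −0.16 without control replicate 2. Genes of fatty acid synthesis rose, with 9 of 14 higher and a median of 0.47 (adjusted p = 0.00253, and adjusted p = 0.958 with an estimated correlation). Beside fads2, its member srebf1, a transcription factor of lipid synthesis, stood at 128 ± 21.0 CPM (SD, n = 4) against 84.2 ± 22.0 (SD, n = 4). Genes of xenobiotic metabolism rose, with 30 of 38 higher and a median of 0.36 (adjusted p = 4.30e-05, and adjusted p = 0.958 with an estimated correlation), 0.14 without control replicate 2, with abcb5 at 0.86 and cyp2k18 at 0.77.

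A further 8 lists passed in AVS low at the preset correlation, each with adjusted p = 0.958 with an estimated correlation. Higher were intestine (21 of 24 members, median 0.55, 0.22 and not called without control replicate 2), exocrine pancreas (17 of 22, 0.23, −0.08 without that library), immune genes (28 of 40, 0.20, then 0.05), sterol sensing and uptake (9 of 14, 0.20, then 0.13) and sterol efflux and bile acids (15 of 20, 0.16, then −0.04), and these 5 calls ended without that library. Lower were neurons (36 of 45, −0.23, −0.11 and not called without control replicate 2), the nuclear genes of the respiratory chain (51 of 61, −0.31) and the mitochondrial genome (13 of 13, −0.25). The respiratory chain call ended without control replicate 4 (−0.05) or AVS low replicate 5 (−0.18), the library with the lowest ribosomal share, and with the trend of fold change with gene length removed its median was −0.16, still called. That for the mitochondrial genome ended without control replicate 4 (−0.11), control replicate 3 (−0.24), AVS low replicate 2 (−0.17) or AVS low replicate 5 (−0.17). Neurons also lost the call without AVS low replicate 2 (−0.14), exocrine pancreas without AVS low replicate 1 (0.27), and sterol efflux without AVS low replicate 1 (0.21), 4 (0.29) or 5 (0.20). Named members were cubn (0.90) and cdx1a (0.65) for intestine, ela2 (1.25) and cuzd1.2 (1.01) for pancreas, and irf1b (1.23) and stat3 (0.71) for immune genes. They also were ldlrb (0.93) and lrp1ab (0.47) for sterol uptake, abca1b (0.92) and abcb11a (0.95) for sterol efflux, and nefmb (−0.42) and chata (−0.66) for neurons. Further ones were uqcrq (−1.43) and cox4i1 (−0.56) for the respiratory chain, and mt-co2 (−0.75) and mt-nd4l (−0.29) for the mitochondrial genome. The number of lists called was 13, and 8 without control replicate 2. Over the 37 lists, 7 members passed adjusted over the list alone and 0 over all genes, and with fry 0 lists passed, with a smallest adjusted p of 0.778.

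**Figure D3:**
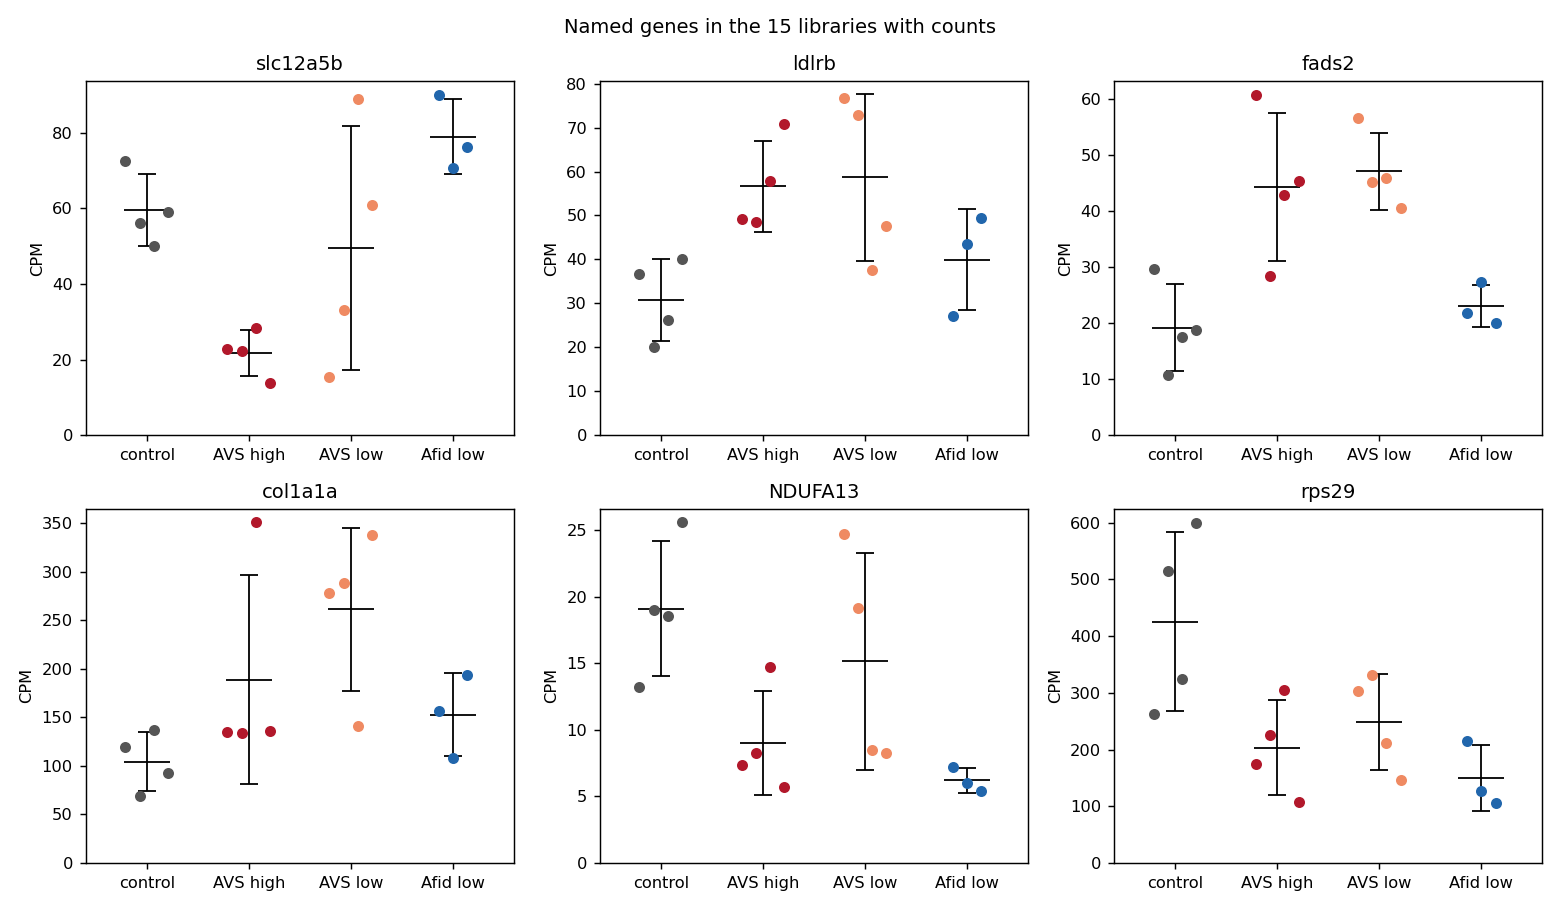
CPM of 6 named genes (y axis, linear scale from 0) by group, 1 point per library, with the group mean and SD as bars. The AVS high libraries lie between 13.7 and 28.3 CPM for slc12a5b, below the 4 control libraries, and the libraries of both AVS doses lie between 28.5 and 60.8 CPM for fads2, where the control lies between 10.8 and 29.7.

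Between the atorvastatin doses, lens genes differed most in the list test. They were higher in AVS high, with 39 of 40 members above AVS low and a median of 0.39 (camera, adjusted p = 1.66e-09 at the preset correlation, adjusted p = 0.842 with an estimated correlation). Ribosomal protein genes (66 of 74 higher, median 0.26), muscle genes (48 of 53, 0.22), nuclear genes of the respiratory chain (55 of 62, 0.19), the mitochondrial genome (11 of 13, 0.29), photoreceptors (38 of 49, 0.14), liver (23 of 28, 0.13) and exocrine pancreas (18 of 22, 0.33) were also higher in AVS high, and immune genes were lower (36 of 41, −0.23), all with adjusted p = 0.842 with an estimated correlation. Without AVS low replicate 5, the library of lowest ribosomal share, 5 in place of 9 lists passed, and the calls for ribosomal proteins (0.11), respiratory chain (0.06), photoreceptors (0.07) and liver (0.09) ended. The calls also ended for respiratory chain (0.10), liver (0.10) and exocrine pancreas (0.01) without AVS high replicate 3, for the mitochondrial genome (0.22) and photoreceptors (0.08) without AVS low replicate 2, for immune genes (−0.12) and photoreceptors (0.07) without AVS high replicate 2, for photoreceptors without AVS high replicate 1 (0.11), and for exocrine pancreas without AVS high replicate 4 (0.31) or AVS low replicate 4 (0.15). Adjusted over the list alone 0 members passed, and over all genes 0.

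The single genes of smallest p between the doses were cyldb, a deubiquitinase gene (log2 difference of AVS high from AVS low −0.98, SE 0.19), gpc1a (−1.48, SE 0.36), zbtb34 (−2.44, SE 0.62), rufy2 (−2.23, SE 0.57) and rhbdl1 (−1.08, SE 0.28), and on the higher side mta3 (1.19, SE 0.32), btg3 (0.76, SE 0.22), uba2 (0.51, SE 0.15), rpl13a (0.83, SE 0.25) and nbr1b (0.49, SE 0.15). Of these 0 passed in edgeR, which called 0 of 20144 genes with a smallest adjusted p of 0.364 and 1095 genes at unadjusted p under 0.05 where chance gives 1007. DESeq2 called 4 genes, all lower in AVS high: si:dkey-239b22.1, zgc:153932, rufy2 and si:ch211-217k17.8. The groups did not overlap in 408 genes, 2.03% where chance gives 2.86%.

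Genes for ribosomes and for the respiratory chain were among those that fell in Afid low by DESeq2, while edgeR called 0 genes. A total of 8 genes fell and 7 rose in the authors' deposited table. The lower ones in the authors' deposited table included NDUFA13 (log2 fold change −1.63, adjusted p = 4.11e-05) and NDUFB1 (−1.55), subunits of respiratory complex I, and the ribosomal proteins rps29 (−1.51), rpl37 (−1.28) and rps21 (−1.07). The higher ones in the authors' deposited table included the slow muscle myosin smyhc2 (1.64), the transporter abcc13 (3.57) and the lipid flippase atp8b1 (1.21).

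In the edgeR fit of Afid low, NDUFA13 stood at 6.43 ± 0.995 CPM (SD, n = 3) against 19.7 ± 5.34 CPM in the control (SD, n = 4), a log2 fold change of −1.62 (SE 0.25). The gene rps29 (ENSDARG00000041232; chromosome 20, 54079341 to 54085949) stood at 155 ± 60.1 CPM (SD, n = 3) against 438 ± 165 (SD, n = 4), a log2 fold change of −1.50 (SE 0.32). NDUFB1 was at −1.54 (SE 0.36), rpl37 at −1.27 (SE 0.30), rps21 at −1.05 (SE 0.26), fkbp3 at −1.20 (SE 0.27) and lhfpl2a at −1.19 (SE 0.27). Genes with higher values were smyhc2 (1.65, SE 0.26), abcc13 (3.51, SE 0.59), atp8b1 (1.23, SE 0.24), akap12a (0.92, SE 0.19) and muc13a (1.59, SE 0.38). None passed: edgeR called 0 of 19399 genes, with a smallest adjusted p of 0.338, 1368 genes at unadjusted p under 0.05 where chance gives 970, 0 genes by limma-voom and 15 by DESeq2. Of the 1368 genes, 697 were higher and 671 lower. The groups did not overlap in 1718 genes, 8.86% where chance gives 5.71%. Without control replicate 4 edgeR called 1 gene, FO704772.2. The DESeq2 count was 0 without Afid low replicate 4, 8 without control replicate 3, 24 without control replicate 4, 41 without Afid low replicate 1 and 60 without control replicate 1.

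Ribosomal protein genes fell in Afid low, with 72 of 74 members lower and a median of −0.57 (camera, adjusted p = 1.13e-28 at the preset correlation, adjusted p = 0.958 with an estimated correlation of 0.82). Of these members, 3 passed adjusted over the list alone against 0 over all genes. Without control replicate 4, which had the highest ribosomal share, the median was −0.32. Nuclear genes of the respiratory chain fell, with 59 of 60 lower and a median of −0.48 (adjusted p = 4.11e-19, and adjusted p = 0.958 with an estimated correlation of 0.76), and −0.24 without control replicate 4. Members of smallest p were uqcrq (−1.99, SE 0.52) and ndufa1 (−1.34, SE 0.36). NDUFA13 and NDUFB1, given above, are not counted here, since their symbols in capitals were not matched to the list. Heart genes rose, with 12 of 14 higher and a median of 0.44 (adjusted p = 0.00425, and adjusted p = 0.958 with an estimated correlation), the call ending without Afid low replicate 1 (0.29). The atrial myosin myh6 was at 1.23 (SE 0.32) and myh7l at 0.73 (SE 0.20), and these 2 passed adjusted over the list alone.

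A further 7 lists passed in Afid low at the preset correlation, each with adjusted p = 0.958 with an estimated correlation. Higher were lens (27 of 40 members, median 0.12), calcium handling (22 of 31, 0.16), intestine (20 of 24, 0.27) and xenobiotic metabolism (29 of 37, 0.24). Lower were photoreceptors (37 of 47, −0.15), neurons (35 of 45, −0.15) and glia (14 of 17, −0.21). Named members were bfsp2 (0.86) and lgsn (0.83) for lens, the muscle calcium channel genes cacna1sa (0.75) and cacna1sb (0.41) for calcium handling, cubn (0.52) and fabp1b.1 (−0.83) for intestine, abcb5 (0.39) and gsta.1 (−1.41) for xenobiotic metabolism, pde6ha (−0.91) and gngt2b (−0.86) for photoreceptors, gap43 (−0.59) and stmn2b (−0.48) for neurons, and the myelin genes plp1b (−0.43) and cldnk (−0.44) for glia. Without control replicate 2 the calls for intestine (−0.01), xenobiotic metabolism (0.06), photoreceptors (−0.06), neurons (−0.03) and glia (−0.07) ended. Without Afid low replicate 1 those for lens (−0.07), intestine (0.23), xenobiotic metabolism (0.21) and neurons (−0.10) ended. Without control replicate 1 those for lens (0.03), intestine (0.24) and xenobiotic metabolism (0.34) ended, and without Afid low replicate 4 those for photoreceptors (−0.09), glia (−0.15) and xenobiotic metabolism (0.27). Without Afid low replicate 2 those for calcium handling (0.16) and xenobiotic metabolism (0.25) ended, and without control replicate 4 that for calcium handling (0.15). Over the 37 lists 7 members passed adjusted over the list alone and 0 over all genes. With fry 0 lists passed, with a smallest adjusted p of 0.778.

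By DESeq2, 9 genes fell and 0 rose in Afid high in the authors' deposited table, 5 of them for ribosomal proteins, with 1817 genes at unadjusted p under 0.05 where chance gives 1291. These calls depend on the adjustment, since an adjusted p of 1 there is read as not given. With the p-values of the authors' deposited table adjusted over all listed genes, 5 genes passed, of which 1 is among the 9 (the entry without a gene symbol), and 0 ribosomal protein genes passed. The other 4 by the p-values of the authors' deposited table were ndufa1 (log2 fold change −1.54) and NDUFA13 (−1.40), subunits of respiratory complex I, si:dkey-239h2.3 (−0.94) and, on the higher side, ankrd52a (2.25). The 9 lower ones in the authors' deposited table were the ribosomal proteins rpl38 (log2 fold change −1.21), rpl36a (−1.09), rps29 (−1.07), rpl37 (−1.05) and rpl23 (−1.001), with ppdpfa (−0.79), ddx47 (−0.68), the phosphatase gene ppp1cbl (−0.58) and 1 entry without a gene symbol (−1.48). Further higher values in the authors' deposited table were slc7a1 (1.70), RAP1GDS1 (0.90), pho (1.18) and fam184b (1.35), with an adjusted p not given, and these 4 did not pass over all listed genes. Which control libraries entered this comparison is not shown in the sources used here. If control replicate 4 did, the control library with the highest ribosomal share, its part in the fall could not be measured without values per library.

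Of the lists in Afid high, ribosomal proteins fell, with 73 of 75 members lower in the authors' deposited table and a median of −0.57 (camera, adjusted p = 1.42e-43 at the preset correlation), and 58 members passed adjusted over the list alone, against 5 by the authors' adjusted p and 0 over all listed genes. Nuclear genes of the respiratory chain fell, with 60 of 61 lower in the authors' deposited table and a median of −0.52 (adjusted p = 5.88e-32), 28 passing adjusted over the list alone, against 0 by the authors' adjusted p and 1 (ndufa1) over all listed genes. NDUFA13, a further respiratory chain gene, also passed over all listed genes but was not matched to this list. Photoreceptors (41 of 47, median −0.31), muscle (38 of 53, −0.16), the mitochondrial genome (12 of 13, −0.14) and skin keratins (17 of 23, −0.24) also passed as lower by the same test on the authors' deposited table at a preset correlation of 0.01, and immune genes (32 of 41, 0.38) and heart genes (12 of 14, 0.29) as higher. Examples in the authors' deposited table were pde6ha (−0.84) and rpe65a (−0.59) for photoreceptors, eno3 (−0.66) and tpma (−0.85) for muscle, mt-co3 (−0.50) and mt-nd3 (−0.42) for the mitochondrial genome, evpla (1.002) and krt91 (−0.49) for skin, mxa (3.59), an interferon-induced gene, and irf1b (−0.655) for immune genes, and myh6 (1.102) and tnnt2a (0.70) for heart, so evpla and irf1b ran against the direction of their lists. An estimated correlation needs values per library, which were not used here. With a preset correlation of 0.1, 3 lists passed, ribosomal proteins, respiratory chain and photoreceptors, and the calls for muscle, mitochondrial genome, skin keratins, immune genes and heart ended. With 0.3, 2 lists passed, ribosomal proteins and respiratory chain. The estimated correlations of these lists were 0.82 and 0.76 in Afid low, and 0.76 and 0.64 in AVS high. Presets of 0.1 and 0.3 lie below these values. The calls that remained therefore do not show that the lists would pass at such a correlation.

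Fold changes of the comparisons are related through the control libraries that they share. For AVS high and AVS low the covariance of log2 fold changes across 20144 genes, which are not independent replicates, was 0.132 (correlation 0.65). Simulated unchanged groups against simulated controls that they share gave 0.0615 (correlation 0.49). With no control library shared the covariance was 0.0628 (correlation 0.24), with a range of 0.0418 to 0.0912 over divisions of the controls. The simulated values here and below hold for shared controls only. None was made for covariances without a shared control library, so the 2 are not to be set against each other. For AVS low and Afid low the covariance was 0.0983 (correlation 0.51), where unchanged groups gave 0.0616. With no control library shared it was 0.0290 (range 0.0020 to 0.045 over divisions of the controls). For AVS high and Afid low the covariance was 0.0533, where unchanged groups gave 0.0611, and −0.0160 with no control library shared (range −0.0377 to 0.0134 over divisions of the controls). Between Afid high and Afid low the correlation was 0.71 and the covariance 0.132, where unchanged groups gave 0.46 and 0.0707. For Afid high with AVS low they were 0.53 and 0.106, where unchanged groups gave 0.50 and 0.0712, and with AVS high 0.27 and 0.0532, where these gave 0.50 and 0.0710. The controls could not be divided for Afid high, which was taken to share the same control libraries. The simulated groups lack differences that move many genes of a library together, as in control replicate 2. They can therefore understate the covariance and the shared calls of unchanged libraries, and do not decide whether a pair shares a response. Calls of the authors' deposited tables shared between comparisons were gh1 and fads2, higher at both AVS doses, where independent lists would share 0.0126 and simulated unchanged groups up to 1. For AVS low and Afid low they were atp8b1 (higher) and si:dkey-239h2.3 (lower), where simulated unchanged groups shared up to 2, for AVS high and Afid low zgc:158463 (higher), where these also shared up to 2, and for both Afid doses rpl37 and rps29 (lower), all per the authors' deposited tables. The Afid doses were matched by symbol, and rpl37 has a further entry in the authors' deposited table of Afid high (−0.57, adjusted p not given).

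The sterol genes and TRP channel genes chosen for the known targets of both compounds did not pass in any comparison. For hmgcrb, which encodes HMG-CoA reductase, the log2 fold change was 0.12 (SE 0.16) in AVS high, 0.13 (SE 0.15) in AVS low and −0.07 (SE 0.14) in Afid low. For sqlea, squalene epoxidase, it was 1.18 (SE 0.54), 1.00 (SE 0.45) and 0.64 (SE 0.50), at 1.28 to 2.88 CPM. The corresponding values were 0.17, 0.22 and −0.09 for hmgcs1, 0.32, 0.08 and −0.44 for cyp51, and −0.02, 0.08 and 0.27 for ldlra. The gene hmgcra was at 1.35 (SE 0.60) in AVS low, with at most 1.21 CPM in each group, and lay below the read filter in AVS high and Afid low, as insig1 did in every fit. For trpv1 the values were 0.24 (SE 0.32), 0.38 (SE 0.31) and 0.15 (SE 0.27), for trpv4 0.22, 0.91 and 0.42, and for trpa1b −0.09, −0.06 and −0.13. In the authors' deposited table of Afid high, hmgcrb was at −0.10, hmgcs1 at −0.11, cyp51 at −0.76, ldlra at 0.10, sqlea at 0.39, hmgcra at 0.38, trpv1 at 0.37, trpv4 at 0.39 and trpa1b at −0.36.

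The other 17 lists passed in no comparison. Cholesterol synthesis had a median log2 fold change of 0.23 in AVS high (adjusted p = 0.0644, camera), 0.25 in AVS low (adjusted p = 0.0739), −0.09 in Afid low and −0.02 in Afid high. TRP channels had 0.22, 0.18, 0.15 and 0.05 in the same order, and muscle wasting −0.01, −0.02, 0.13 and 0.07. Coenzyme Q synthesis had 0.06, 0.01, −0.14 and −0.12, fatty acid oxidation 0.07, 0.10, −0.05 and −0.02, and lipoproteins 0.13, 0.12, 0.05 and 0.15. Oxidative stress had 0.10, 0.07, −0.06 and −0.09, and heat shock and the unfolded protein response 0.11, 0.07, −0.12 and −0.10. Hair cells had −0.10, 0.00, 0.08 and 0.11, red blood cells 0.17, 0.05, 0.11 and 0.05, and the circadian clock −0.02, −0.01, 0.02 and −0.06. Immediate early genes had 0.01, 0.08, −0.15 and −0.10, the glucocorticoid axis −0.09, 0.03, 0.04 and −0.05, and thyroid and pituitary genes −0.02, 0.07, −0.07 and −0.10. The sex steroid pathway had 0.06, 0.26, 0.12 and 0.02, the cell cycle 0.06, 0.23, −0.24 and −0.13, and hatching gland and yolk, with 1 tested gene, 0.13, 0.04, −0.48 and −0.40. The direction of the test went against the sign of the median for thyroid and pituitary, sex steroids, immediate early genes and muscle wasting in AVS high. It also did so for hair cells, coenzyme Q and heat shock in AVS low, and for glucocorticoids, circadian clock, sex steroids and thyroid and pituitary in Afid low. In Afid high this was so for sex steroids, and between the AVS doses for circadian clock, fatty acid oxidation and heart. The mean alone differed in sign from the median for immune genes, cell cycle and mitochondrial genome in AVS high, heart and liver in AVS low, glucocorticoids and cell cycle in Afid high, and oxidative stress, lipoproteins and cholesterol synthesis between the AVS doses.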

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

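All explanations and splits of the libraries below, and the bounds that decided them, were chosen after the results were seen, and the bound for control replicate 4 was revised again after its values were seen, whereas the rule for libraries that stand apart was not.

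Within groups of 4 libraries, 1 library stood apart from the other 3 in 24 of 447 groups of values, where chance gives 22.4, so single cases carry little weight. Control replicate 2 was low in the scores for sterol sensing and uptake (−0.53) and sterol efflux and bile acids (−1.105), low in CPM of ldlra (63.4) and abca1b (19.8), and high in CPM of the neuronal gap43 (35.7) and the myelin gene plp1b (86.5). AVS low replicate 4 was low in the scores for cholesterol synthesis (−0.15), xenobiotic metabolism (−0.0733) and exocrine pancreas (−0.55) and in CPM of the elastase ela2 (75.5), and high in CPM of hspa4b (6.38) and mt-co2 (4393). AVS high replicate 1 was high in the score for muscle wasting (0.20) and in CPM of grk1b (30.9), guca1c (39.5) and rpl13a (267). AVS high replicate 2 was low in the TRP channel score (−0.245), AVS high replicate 3 was high in CPM of col1a1a (351), and AVS high replicate 4 was low in CPM of mpp2a (11.3) and gpc1a (1.28). Control replicate 1 was high in the muscle wasting score (0.0845) and in CPM of slc17a6a (36.6), control replicate 3 was high in CPM of mta3 (15.6), and AVS low replicate 1 was high in the red blood cell score (0.43).

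Chance could not be excluded for the counts above 0 of a comparison, since at least 4 of the 35 splits of its libraries gave as many genes or lists. For the counts of 0 genes called by edgeR, all 35 splits must give as many, so these 35 decide nothing, with 0 as the highest other in AVS high, 1 in AVS low, 1 in Afid low and 347 between the AVS doses. At unadjusted p under 0.05, 5 splits gave at least the 1657 genes of AVS high (highest other 2602), 5 the 1949 of AVS low (3198), 5 the 1368 of Afid low (2715) and 16 the 1095 between the doses (3553). With DESeq2, 4 splits gave at least the 61 genes of AVS high (highest other 513), 5 the 43 of AVS low (617), 6 the 15 of Afid low (438) and 17 the 4 between the doses (713). For lists called, 18 splits gave at least the 10 of AVS high (highest other 20), 15 the 13 of AVS low (19), 29 the 10 of Afid low (20) and 15 the 9 between the doses (18). Splits with several times the real count may point to a structure of the libraries other than the exposure, and its cause was not tested.

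Higher intestine genes in AVS high, AVS low and Afid low may come from control replicate 2, whose score for this list was −1.73. Without it the calls remained in 0 of the 3 comparisons, and the medians went from 0.38, 0.55 and 0.27 to 0.05, 0.22 and −0.01. An effect of the exposures on this list stays open, since the highest median without that library was 0.22 and was not called. The pooled SD between libraries of 0.56 includes control replicate 2, so it overstates the spread without that library and cannot decide this. For the exocrine pancreas list in AVS high, the median fell from 0.74 to 0.32 without control replicate 2 and the call remained. A part from that library and a part from the exposure cannot be told apart. The pooled SD between libraries was 0.71, which also includes control replicate 2.

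Lower ribosomal protein and respiratory chain genes in Afid low were weighed against gene length, control replicate 4 and chance. With the trend of fold change with length removed, the medians were −0.53 (SD 0.32 over members) and −0.42 (SD 0.39), in place of −0.57 and −0.48. The trend with length thus accounts for little of the fall seen in these libraries. Both lists were still called at the preset correlation. The SD over members does not measure the spread between libraries (pooled SD of the list scores 0.39 and 0.33), so a fall beyond that spread is not shown. Without control replicate 4 they were −0.32 and −0.24, both called at the preset correlation but smaller than 2 standard errors of a difference in the list score between groups (0.63 and 0.54), so the share of that library cannot be told apart from an effect of afidopyropen. Chance could not be excluded either, since 6 of 35 splits gave a ribosomal median as far from 0 as −0.57 (highest other 0.76), and 6 of 35 a respiratory chain median as far as −0.48 (highest other 0.69).

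The 53 genes lower in AVS high in the authors' deposited table had a median log2 fold change of −1.13 (SD 0.31 over genes). With the length trend removed it was −1.105 (SD 0.31), which argues against that trend, weak and upward (Spearman 0.09), as the whole cause. Their median genomic span was 61920 bases against 17040 over all tested genes, and an effect of span was not tested. The neuron list had a median of −0.14 (SD 0.33), with 0 of its 45 members as low as the median of the 53 genes. These genes were picked as lower in the same data, so their median lies below that of an unpicked list in any case. This comparison therefore does not decide on less neural tissue. Differences between libraries of 1 group are of a sufficient size in AVS low. There the median of these genes differed by 2.06 between the 4 libraries, from −1.66 in replicate 1 to 0.40 in replicate 4. These libraries were also exposed to atorvastatin, so their spread is not apart from the drug. The libraries lay closer together in the control (−0.13 to 0.40) and in Afid low (0.23 to 0.28). An effect of atorvastatin may be present as well, but at the lower dose the median over these genes was −0.36 with libraries on both sides of the control mean, so the dose and the differences between libraries cannot be told apart.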

How the results depend on the processing

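The length correction, DESeq2 with libraries left out, the adjustment over all listed genes, the preset correlations of 0.1 and 0.3 and the fit of the block's libraries without the block were chosen after seeing the data, and the cause of the changes below was not tested. In edgeR, 0 genes passed in AVS high, AVS low, Afid low and between the AVS doses under DESeq2 size factors, limma-voom (not run between doses), the length correction and all libraries in 1 fit or, between doses, the pair of groups alone. DESeq2 called 61, 43, 15 and 4 genes, and no low-count filter 2 in AVS high. With 1 library left out, edgeR called 0 to 1 genes in Afid low, and DESeq2 2 to 290 genes in AVS high, 3 to 796 in AVS low and 0 to 60 in Afid low. Lists called ranged from 3 to 13 in AVS high, 8 to 14 in AVS low, 8 to 12 in Afid low and 5 to 12 between the doses, and 0 passed in each with an estimated correlation or fry. Over all listed genes, the authors' deposited p-values for Afid high gave 5 genes, 1 of them among the 9 called and 0 for ribosomal proteins. The same adjustment gave 47 genes in AVS high, 32 in AVS low and 13 in Afid low, in place of 61, 43 and 15. The lists called in Afid high numbered 3 and 2 at preset correlations of 0.1 and 0.3. Both presets lie below the estimated correlations of the ribosomal and respiratory chain lists in every comparison with counts. The Afid high count could not be recomputed with the other tools and settings, which need counts per library, nor Afid high against Afid low, and the pseudocount and low-value filter for normalized values were not needed.

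With libraries left out in turn, medians that changed sign ranged from −0.0581 to 0.29 for liver in AVS high, −0.0388 to 0.34 for sterol efflux and −0.0775 to 0.74 for exocrine pancreas in AVS low, and −0.00792 to 0.49 for intestine and −0.0682 to 0.51 for lens in Afid low. Values of genes that changed sign ranged from −0.27 to 0.0274 (trpa1b) and −0.21 to 0.12 (ldlra) in AVS high, −0.12 to 0.19 (ldlra), −0.20 to 0.30 (cyp51) and −0.17 to 0.0403 (trpa1b) in AVS low, and −0.30 to 0.0930 (hmgcs1) in Afid low. With no control library shared, the covariance and correlation of fold changes moved to 0.0628 and 0.243 for AVS high with AVS low and 0.0290 and 0.117 for AVS low with Afid low, and turned to −0.0160 and −0.0569 for AVS high with Afid low. These are means over 6 divisions of the controls. In the same order the covariance ranged from 0.0418 to 0.0912, from 0.0020 to 0.045 and from −0.0377 to 0.0134, so the sign for the last pair is not settled. For 137 pairs of a named gene and a comparison, 1036 values under other alternatives held 996 on the same side of the threshold and 40 that newly passed. Genes named because the authors' DESeq2 called them pass under DESeq2 here by that choice, so these 40 are in part fixed in advance. For 42 pairs of a called list and a comparison, 275 such values held 215 that stayed called and 60 that did not. Fry, which ended all of these list calls, is not among the 275 values. The estimated correlation, which also ended all of them, is among the 275 and makes up most of the 60. The 215 that stayed called all keep the preset correlation, so they are no support apart from it.

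The replicate numbers are not shown to pair the libraries: of 13 pairs of equal number, 1 had a correlation of deviations over 0.1 (range −0.256 to 0.134) and 1 was best with its own number. With the replicate number as a block edgeR called 0 genes in each comparison, and lists called were 12 in AVS high, 13 in AVS low, 11 in Afid low and 7 between the doses. Depth limits genes of a few reads, such as hmgcra.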

Other observations

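The test of the fatty acid list below and its bound were chosen after the result was seen.

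Growth hormone, gh1, and fads2 passed at both AVS doses in the authors' deposited tables. In the fits here gh1 stood at 22.2 ± 16.9 CPM (SD, n = 4) in AVS high against 5.33 ± 1.398 (SD, n = 4) in the control, and at 21.9 ± 15.4 (SD, n = 4) in AVS low against 5.59 ± 1.47 (SD, n = 4). Its values in AVS high ranged from 5.98 to 42.1 CPM, and the lowest lay within the control range of 4.39 to 7.36 CPM. In Afid low it stood at 11.7 ± 10.6 CPM (SD, n = 3), and fads2 at 24.0 ± 3.87 (SD, n = 3) against 19.8 ± 8.07 in the control (SD, n = 4).

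On the first principal component, AVS high replicate 4 (47.6), AVS low replicate 1 (38.5) and AVS high replicate 2 (24.3) lay furthest from the control libraries, which ranged from −13.9 to −4.66. Fold change rose weakly with gene length across genes, with a Spearman correlation of 0.09 in AVS high, 0.18 in AVS low and 0.16 in Afid low.

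A hypothesis is that atorvastatin at the lower dose may raise the transcripts of fatty acid synthesis, whose list had a median of 0.47 in AVS low. The median of this list was also above 0 in AVS high (0.11, camera adjusted p = 0.0684), Afid low (0.29, adjusted p = 0.0568) and Afid high (0.24, adjusted p = 0.0791), so a rise particular to AVS low or to atorvastatin is not shown. The difference between the AVS doses was not called (adjusted p = 0.277), and that between the compounds was not tested. Of the 35 splits of the AVS low and control libraries, 1 gave a median as far from 0, the real one at 0.472, with 0.468 as the highest other. Its permutation p of 0.029 is the smallest that 35 splits can give. The list was picked after its result was seen, so this rank does not exclude chance. Over the 148 pairs of a list and a comparison, 4 had the real split at the top where chance gives 4.23, so this list does not stand out among those tested.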
